A study of Mus musculus with 6 samples.

How the data were processed

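Total RNA of freshly sorted mouse hematopoietic stem cells (HSCs) was sequenced on an Illumina HiSeq instrument after RNA extraction with the Qiagen RNeasy Micro kit and library preparation with the TruSeq RNA kit, per the labels. The cells came from the bone marrow of female C57BL/6 mice that were naive or infected with Mycobacterium avium. They were gated as side population cells (cells that pump out a DNA dye) that were Kit positive, Sca-1 positive, lineage negative and CD150 positive. The labels list 6 libraries, 3 per group. In each group, libraries 1 and 2 are described as technical replicates of biological replicate 1, from mice aged 5 months, and library 3 belongs to biological replicate 2, from mice aged 3 to 4 months. Each group therefore holds 2 biological replicates. How many mice were pooled for a replicate and how long the infection lasted are not given in the sources used here.

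The file analysed is a whole-series table in which the authors deposited 1 FPKM value (a fragment count scaled to transcript length and to the total of mapped fragments) per gene for each group, per the file headers. The same table holds the authors' log2 fold change, p-value and q-value for infected over naive, per the file headers. The submitters' processing notes name the genome build mm9 and the tool DESeq, without a version or a role. The table's layout, with a locus string, joined gene names and coded extreme folds, resembles the output of Cuffdiff, so it is open whether DESeq gave the authors' p-values. The aligner, the gene annotation, the program that gave the FPKM, the model behind the p-values and whether technical replicates entered it as separate samples are not given in the sources used here. How the libraries of a group were combined into its FPKM is not given either. Values per library and read counts were not used here. The depth behind each value is therefore unknown, no interval or detection floor is given, and no value carries an SD or a number of replicates.

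The table has 30385 gene rows, 451 of which name several genes. The deposited q-values under 1 belong to 11132 genes, and a Benjamini-Hochberg adjustment of the deposited p-values over these genes gave the deposited q-values to within a relative difference of 6.73e-06. A further 5480 genes had a deposited p-value under 1 but stood outside the adjustment, and the highest FPKM among them was 0.325. Another 2976 genes were above 0 FPKM in both groups but carried a deposited p-value of 1 outside the adjustment. They are called not tested here, and the reason is not given in the sources used here. Where both FPKM were above 0 and the gene was in the adjustment, the sign of the deposited fold followed the FPKM columns. Fold changes against a group listed at 0 are coded in the table as extreme values and were not used as folds. A value of 0 can be a failed estimate: Rb1, chosen after its values were seen, is a broadly used gene listed at 0 in both groups.

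The design fixed before the data were examined foresaw a model on values per library, a set test on gene lists, the agreement of both biological replicates, the spread of technical replicates and repeats without single samples. The table has no values per library, so none of these was run. The test reported is the authors' own, taken as deposited, with a gene called at q under 0.05. No p-value was computed across genes, which are not replicates. Folds were taken from the FPKM columns. For ranking genes and for gene lists, the log2 ratio of infected + 1 over naive + 1 FPKM was used. This pseudocount of 1 FPKM understates the change of low genes. Genes at 1 FPKM or more in at least 1 group were kept for list medians (11578 genes, of which 9001 were in the authors' adjustment). Their median log2 ratio was -0.04, so no shift was removed.

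The 30 gene lists were fixed before the data were examined, from general knowledge of the cell type and infection, and not from these libraries. For each list the members called higher and lower were counted in 2 ways, over all genes with the deposited q-values and adjusted over the list alone. The median log2 ratio of the kept members was placed among the medians of 10000 random lists of the same size, drawn from kept genes in 20 bins of mean FPKM. Its percentile describes these pooled values and is not a test. A list with fewer than 3 kept members got no percentile. On simulated log2 ratios for the 11578 kept genes, a list of genes shifted up by 1 lay at percentile 100 and a list shifted down by 1 at percentile 0. Of 100 simulated random lists, 7 lay outside the central 95%. In a simulated adjustment over 11132 genes, the changed genes were shifted so far that their recovery was nearly sure. It recovered 200 of 200 changed genes and called 8 others. That checks the computation and not the sensitivity of the authors' test.

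Named genes follow a rule fixed before the data were examined. It takes the 12 genes with the largest change in each direction among called genes that reach 5 FPKM in the higher group and carry a gene symbol, up to 4 members per list with the smallest deposited p-value, and a fixed set of sort gate, interferon, myeloid and cell cycle genes. The rule's condition of an equal sign in both biological replicates was not applied, as the table does not resolve them. Some genes that the rule names are not reported here. Other genes named are said to be chosen after their values were seen. Gene names are those of the table. Coordinates are the authors' mm9 spans. Their lengths matched a transcript of the same name in the GRCm38 annotation for 11146 genes when starts were read as counted from 0, against 329 when read as counted from 1, so 1 was added to each start. The GRCm38 annotation (GENCODE vM21) gave no coordinates and served for that comparison and for exonic lengths. Spans can cover several neighbouring genes. Near-identical gene families (immunoglobulin segments, H2, Gbp and globin genes) share reads, and their values are uncertain to the extent that the authors' program divided such reads.

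Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter or a filter at 5 FPKM, and an added requirement of a 2-fold change. Chosen after seeing the data were q under 0.01 and under 0.10, an adjustment over every gene with a deposited p-value under 1, leaving out immunoglobulin segments, lists limited to genes in the authors' adjustment, centring on the median ratio, and random lists without matching. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.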

Results

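Transcriptomes of HSCs from naive and Mycobacterium avium infected mice were compared to ask how a mycobacterial infection changes gene expression in these cells. Each group is represented by a single FPKM value per gene in the authors' deposited table. The sum of FPKM was 232288 in naive and 230973 in infected HSCs. At 1 FPKM or more stood 11359 genes in naive and 11339 in infected cells. The 100 most abundant genes held 22.1% of the naive and 22.8% of the infected total. The spread between replicates cannot be seen in pooled values, so each difference rests on the authors' own test.

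HSCs of infected mice carried more transcripts for antigen presentation and interferon-induced defence, and fewer for several immediate early genes and for Mpo and Elane. In the authors' deposited table, 163 of 11132 genes had a q-value under 0.05. Of these, 98 rose in infected HSCs and 65 fell. The risers moved further: the median change of called genes was 1.77-fold upward over 94 genes and 1.32-fold downward over 61 genes with FPKM above 0 in both groups. A change of at least 2-fold was reached by 39 of these risers and by 5 of the fallers. A further 4 called genes were listed at 0 in naive cells and another 4 at 0 in infected cells.

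**Figure D1:**
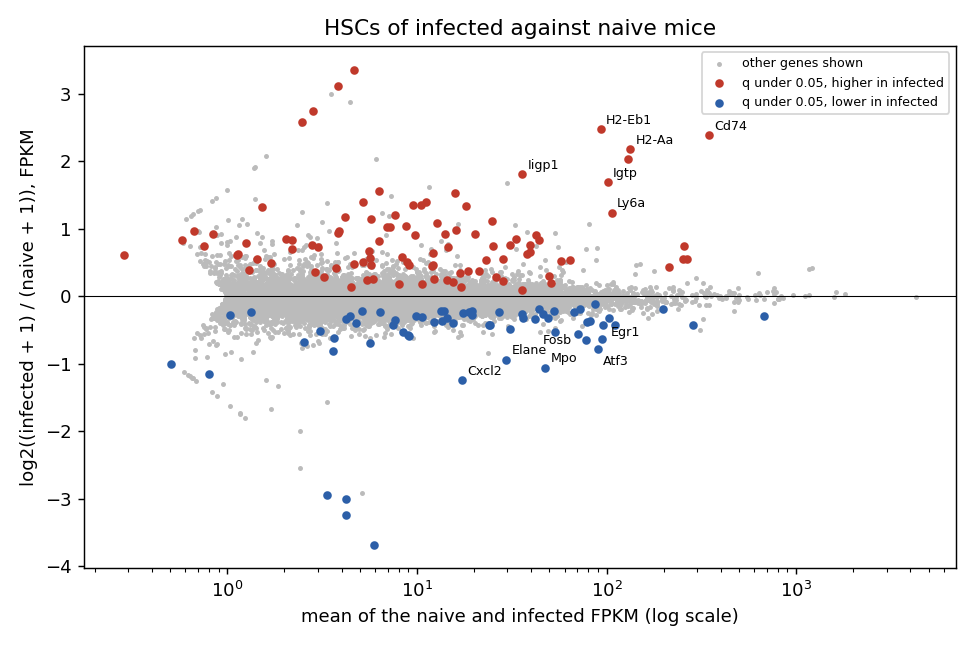
Log2 ratio of infected over naive FPKM (pseudocount of 1) against the mean of both FPKM values on a log scale, 1 point per gene at 1 FPKM or more or called. Red points are the 98 genes called higher and blue points the 65 called lower at q under 0.05 in the authors' deposited table; labelled class II genes reach the highest ratios among abundant genes.

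The largest folds among called genes above 5 FPKM in both groups were in genes of MHC class II, the molecules that present extracellular antigen to helper T cells. H2-Eb1 rose from 27.7 to 159 FPKM, a 5.74-fold change, and Cd74, the invariant chain that chaperones class II molecules (mm9 chromosome 18, 60963502 to 60972300), rose from 111 to 585 FPKM. H2-Aa rose 4.60-fold to 218 FPKM and H2-Ab1 4.17-fold to 209 FPKM. The authors' deposited table lists all 4 of these at a q-value of 0. H2-DMb1, part of the complex that loads peptides, rose 2.92-fold to 16.6 FPKM (q = 4.4e-08 in the authors' deposited table). Of the 14 class II members in the authors' adjustment, 9 rose and none fell, and adjusted over the list alone 11 rose. The list's median log2 ratio was 1.12, at percentile 100 of random lists. Ciita, the master activator of class II transcription and chosen after its values were seen, rose from 0.309 to 1.19 FPKM (q = 4.8e-05 in the authors' deposited table). Marker lists of B cells, monocytes and macrophages, and dendritic cells had median log2 ratios of 0.02, -0.02 and -0.06, inside the central 95% of random lists. These medians cover only 4 of 17, 13 of 24 and 6 of 13 markers. All of those already stood at 1 FPKM or more in naive cells, so the medians do not cover markers absent there. Without a filter on low values, the B cell and plasma cell median was 0.07, at percentile 98.0 and above that range.

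Interferon-inducible GTPases, proteins that act against intracellular pathogens, rose nearly as a block. Of 16 members in the authors' adjustment, 15 rose and none fell, with the same count adjusted over the list alone. Their median log2 ratio was 1.15, a 2.22-fold change, at percentile 100. Iigp1 rose 3.66-fold from 15.3 to 56.2 FPKM and Igtp 3.28-fold from 47.3 to 155 FPKM. Among guanylate-binding proteins, Gbp3 rose 3.15-fold, Gbp4 2.87-fold and Gbp6 2.85-fold, and the authors' deposited table lists each at a q-value of 0.

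Calls among interferon-stimulated genes all went upward. Of 39 members in the authors' adjustment, 12 rose and none fell, and adjusted over the list alone 17 rose. The list's median log2 ratio was 0.35 (percentile 100), and 46 of its 47 kept members had a ratio above 0. Stat2 rose 1.62-fold, Rnf213 1.48-fold and the nucleic acid sensor Zbp1 2.84-fold, with q-values of 0.000169, 2.6e-08 and 0.00025 in the authors' deposited table. Irf1, a transcription factor induced by interferon, stood at 41.3 FPKM in naive and 69.4 FPKM in infected cells, but was not tested by the authors, so this 1.68-fold difference has no test behind it.

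MHC class I presentation showed the same direction, with fewer members tested. The median log2 ratio over its 25 kept members was 0.48 (percentile 100), and 24 of them had a ratio above 0. The authors' adjustment held 11 of them, of which 3 rose and none fell, while adjusted over the list alone 8 rose. H2-Q4 rose 1.47-fold to 301 FPKM, Nlrc5, an activator of class I genes, 1.70-fold to 31.8 FPKM, and the immunoproteasome subunit Psmb8 1.44-fold to 67.6 FPKM, with q-values of 0, 1.1e-09 and 2.5e-06 in the authors' deposited table. The other 14 members were not tested by the authors.

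Genes of interferon receptors and signalling regulators gave a single call. In the authors' deposited table, 1 of 19 members rose and none fell (2 rose adjusted over the list alone). That gene was Socs1, a feedback inhibitor of cytokine signalling, which rose 1.73-fold to 18.4 FPKM (q = 0.026 in the authors' deposited table). Batf2, an interferon-induced transcription factor, stood at 2.01 FPKM in naive and 4.87 FPKM in infected cells and did not pass over all genes (q = 0.0745 in the authors' deposited table), though it passed adjusted over the list alone (0.0111). The receptor subunit Ifngr1 stood at 169 and 143 FPKM and Ifngr2 at 6.62 and 9.20 FPKM in naive and infected cells, with q-values of 0.994 and 0.328 in the authors' deposited table. Irf8 differed from 4.74 to 5.66 FPKM without passing. The list's median log2 ratio of 0.08 lay at percentile 99.95, a position that it lost when only genes at 5 FPKM or more were kept (0.02, percentile 94.6).

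The TNF and NF-kB response list went both ways. Of 31 members in the authors' adjustment, 6 rose and 1 fell, and adjusted over the list alone 8 rose and 2 fell. Nfkbie, an NF-kB inhibitor, rose 2.28-fold, the NF-kB cofactor Bcl3 1.95-fold and the chemokine Cxcl16 1.46-fold (q = 9.1e-08, 2.3e-10 and 0.000489 in the authors' deposited table). The faller was Cxcl2, a chemokine that attracts neutrophils (mm9 chromosome 5, 91332897 to 91334935), which fell from 24.8 to 9.91 FPKM, a log2 change of -1.32 listed at a q-value of 0 in the authors' deposited table. The median log2 ratio was 0.10 (percentile 100). Among pattern recognition and inflammasome genes 1 of 20 rose, Tmem173, the adaptor of cytosolic DNA sensing, 1.31-fold (q = 0.0304 in the authors' deposited table), the same count held adjusted over the list alone, and the median of -0.02 lay at percentile 66.5. With only genes at 5 FPKM or more, that median was 0.07, at percentile 99.1 and above the random range.

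**Figure D2:**
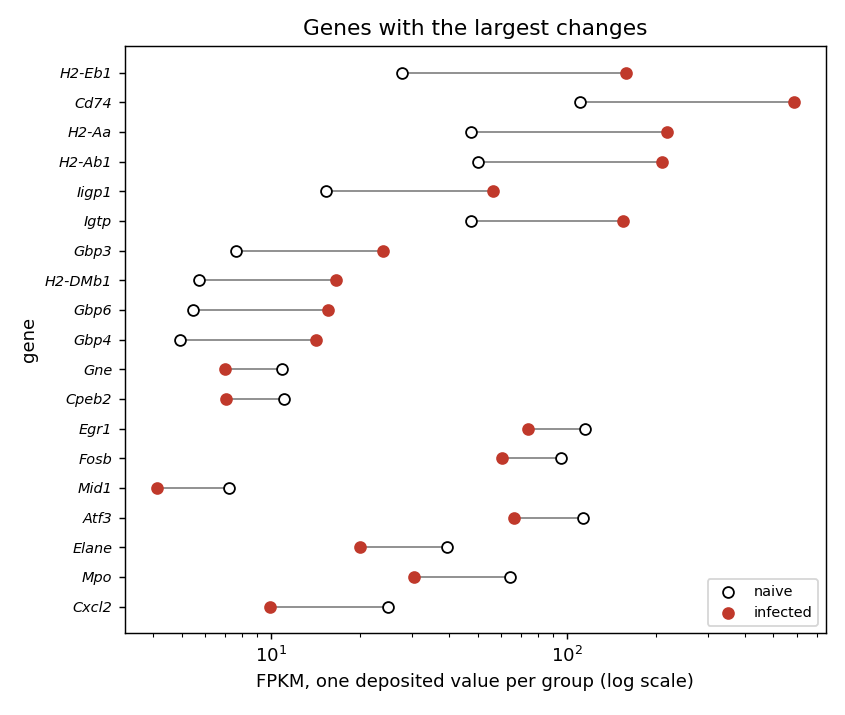
FPKM of naive (open) and infected (red) HSCs on a log axis for the genes with the largest changes in each direction, leaving out those listed at 0 in a group; each point is the authors' single value per group, with no error. Cd74 ends at 585 FPKM and Mpo at 30.4 FPKM in infected cells.

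Among immediate early genes, transcription factors and regulators that cells induce within minutes of a stimulus, calls went downward only. Of 25 members in the authors' adjustment, 5 fell and none rose, and adjusted over the list alone 6 fell. Atf3 fell 1.72-fold from 114 to 66.1 FPKM, Fosb 1.58-fold from 95.9 to 60.6 FPKM and Egr1 1.56-fold from 115 to 74.0 FPKM, with q-values of 0.000169, 0.00199 and 0.00424 in the authors' deposited table. Dusp1 fell 1.29-fold to 71.7 FPKM (q = 0.0136 in the authors' deposited table). The median log2 ratio over 31 kept members was -0.22, at percentile 0, and 22 of them had a ratio below 0. Dissociation and sorting of cells can also induce these genes, and the list was fixed under both names. It also holds the heat shock genes Hspa1a, Hspa1b, Hsp90aa1 and Hspa8, which all stood higher in infected cells.

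The neutrophil granule protein genes Mpo and Elane fell. Mpo, myeloperoxidase (mm9 chromosome 11, 87607083 to 87617915), fell 2.12-fold from 64.4 to 30.4 FPKM and Elane, neutrophil elastase, 1.97-fold from 39.3 FPKM, listed at q-values of 0 and 0.00027 in the authors' deposited table. Ctsg, another granule protease, stood at 11.8 and 7.33 FPKM and did not pass (q = 0.465 in the authors' deposited table). Over the myeloid commitment list as a whole, 2 of 23 members fell and 1 rose, also when adjusted over the list alone. The riser was Plac8, from 29.7 to 46.7 FPKM, and the median log2 ratio of -0.06 lay at percentile 23.4. The myeloid regulators Cebpa (3.11 and 2.69 FPKM) and Cebpb (47.5 and 50.1 FPKM) did not pass. None of 5 basophil and mast cell markers passed. Over the 4 kept markers the median log2 ratio was -0.56, at percentile 0.06, but without a filter on low values the list's median was -0.07, at percentile 8.50, inside the random range. Prss34, a basophil protease, stood at 4.02 and 2.10 FPKM. Neutrophil markers were abundant in both groups, with Ngp at 193 and 174 FPKM and Camp at 87.1 and 73.4 FPKM in naive and infected cells, and none of 16 passed (median log2 ratio -0.04, percentile 41.4).

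Other genes among the largest decreases were Mid1 (1.76-fold), Cpeb2, a regulator of translation (1.58-fold), and Gne, a sialic acid synthesis enzyme (1.55-fold), with q-values of 0.0207, 4.8e-12 and 0.0129 in the authors' deposited table. Immunoglobulin segments were called in both directions. Igkv4-57-1 was listed at 0 in naive and at 5.69 FPKM in infected cells, as was another kappa segment at 0 and 9.26 FPKM, whereas Igkv14-126, Ighv1-7 and Igkv6-32 were listed at 11.8, 8.46 and 6.70 FPKM in naive and at 0 in infected cells. The third riser with an immunoglobulin name, chosen after its values were seen, was the class-switched constant gene Ighg2c. It was listed at 0 in naive and at 4.96 FPKM in infected cells (q = 8.3e-08 in the authors' deposited table). Called rows under other names, chosen in the same way, lay nearby and were not counted as immunoglobulin segments. Gm16637 (0 in naive and 7.67 FPKM in infected cells) lay between the kappa segments that rose. Gm16858 (8.33 and 0.166 FPKM) lay near Ighv1-7. Over 143 rows picked by the start of their names, as variable segments or heavy chain constant genes, FPKM summed to 98.0 in naive and 70.9 in infected cells. This pick leaves out light chain constant genes such as Igkc and admits any other gene whose name starts alike. The sums are therefore not the immunoglobulin total.

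Genes that define HSCs were called in both directions. In the HSC identity list, 1 of 33 members rose and 1 fell in the authors' deposited table, and 2 rose and 2 fell adjusted over the list alone. Gfi1b, a transcription factor of stem cells and platelet precursors, rose 1.51-fold to 5.62 FPKM (q = 0.000495 in the authors' deposited table). The faller was Egr1, which is also in the immediate early list. Clca1 (2.07 and 3.56 FPKM) and Meis1 (28.1 and 22.6 FPKM) passed adjusted over the list alone only. The median log2 ratio of -0.05 lay at percentile 17.7. Among the sort gate genes, Ly6a, which encodes Sca-1, the protein gated on (mm9 chromosome 15, 74825308 to 74828064), rose 2.38-fold from 62.9 to 150 FPKM (q = 3.7e-12 in the authors' deposited table). It was 1 of 5 tested, also adjusted over the list alone, and none fell. The list also holds Cd34, Flt3 and Cd48, which the gate given above does not name. Kit stood at 64.3 and 50.1 FPKM, Flt3 at 7.51 and 6.75 FPKM in naive and infected cells, and Cd34 at 56.6 FPKM in infected and 1.06-fold higher in naive cells, and these were not tested by the authors. Slamf1, which encodes CD150 (3.32 and 3.12 FPKM), the dye pumps Abcg2 (18.1 and 16.4 FPKM) and Abcb1a (1.44 and 1.06 FPKM), and Cd48 (0.703 and 0.908 FPKM) did not pass. The gate list's median was -0.13 (percentile 3.65).

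In the lymphoid priming list, 2 of 11 members rose and none fell in the authors' deposited table, and 3 rose and 3 fell adjusted over the list alone. Ltb, a cytokine of the TNF family, rose 1.49-fold to 33.9 FPKM (q = 0.0244 in the authors' deposited table), and a row joining Il2rg with neighbouring gene models rose 1.46-fold. The median of -0.07 lay at percentile 20.2. For megakaryocyte-erythroid priming, 1 of 24 rose, Mfsd2b, 1.41-fold to 3.40 FPKM (q = 0.00489 in the authors' deposited table), the same count held adjusted over the list alone, and the median log2 ratio of 0.08 lay at percentile 99.93. Markers of erythroid cells, which the lineage gate should remove, gave calls both ways. Hba-a2 rose 2.07-fold to 21.6 FPKM and Bpgm fell 1.30-fold to 68.2 FPKM (q = 0.0421 and 0.00137 in the authors' deposited table). Adjusted over the list alone, 2 rose and 1 fell of 12. The globin genes Hba-a1 (10.5 and 18.8 FPKM in naive and infected cells) and Hbb-b1 (34.1 and 44.1 FPKM) did not pass over all genes. Of the 7 kept erythroid markers, 5 had a ratio above 0 and 2 below. Their median was 0.36, at percentile 99.98, and 0.09 without a filter on low values, still above the random range. Carry-over of erythroid cells into the infected sort was not tested.

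Cell cycle lists gave at most 1 call each over all genes. Of all tested genes 1.46% were called, so counts this small do not set these lists apart. None of 29 DNA replication genes passed, and 1 of 28 mitosis genes did, the centromeric histone Cenpa, which fell 1.27-fold to 36.9 FPKM (q = 0.00537 in the authors' deposited table). Their median log2 ratios were 0.02 (percentile 98.2) and -0.01 (percentile 80.6), and adjusted over each list alone the counts were the same. With only genes at 5 FPKM or more, the DNA replication median changed sign to -0.0062. Of 23 quiescence and cell cycle inhibitor genes 1 fell, Egr1 (2 adjusted over the list alone), with a median of -0.06 at percentile 14.4. Egr1 is also in the HSC identity and immediate early lists, so their counts share this fall. Ccnd1 (19.3 and 19.7 FPKM) was not tested by the authors, and Cdkn1a (66.2 and 56.5 FPKM) and Cdkn1c (12.1 and 11.5 FPKM) did not pass. Among p53 targets and apoptosis genes 1 of 24 fell, the kinase Plk2, 1.47-fold to 57.3 FPKM (q = 0.0129 in the authors' deposited table), also adjusted over the list alone, while the list's median was 0.05 (percentile 99.85).

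Metabolic and structural lists held no called gene. None of 60 ribosomal protein genes, 66 oxidative phosphorylation genes, 16 glycolysis genes and 19 adhesion and homing genes passed in the authors' deposited table, and none did adjusted over each list alone. Median log2 ratios were 0.02 for ribosomal proteins (percentile 99.92), 0.02 for oxidative phosphorylation (percentile 99.95), 0.0052 for glycolysis (percentile 89.3) and -0.02 for adhesion and homing (percentile 60.3). The median over all kept genes was -0.04.

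The remaining lists of other cell types gave at most 1 call each over all genes. With 1.46% of all tested genes called, such counts do not set these lists apart. B cell and plasma cell markers held none of 12 (1 fell adjusted over the list alone), with a median over 4 kept markers at percentile 77.0 (98.0 without a filter on low values) and 4 of 17 markers at 1 FPKM or more in naive cells. For monocytes and macrophages 1 of 16 fell, the scavenger receptor Cd163, from 1.22 to 0.834 FPKM (q = 0.000874 in the authors' deposited table), with a median at percentile 56.5 and 13 of 24 markers at 1 FPKM or more in naive cells. For dendritic cells 1 of 6 fell, Tcf4, a transcription factor that HSCs also express, 1.19-fold to 16.0 FPKM, with a median at percentile 37.2 and 6 of 13 markers at 1 FPKM or more. Both counts were the same adjusted over each list alone. None of 7 T cell, 2 NK cell and 6 endothelial and stromal markers passed. The median log2 ratio was -0.04 for T cell markers (percentile 47.7) and 0.03 for endothelial and stromal markers (percentile 83.0), and only 1 NK cell marker was kept.

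**Figure D3:**
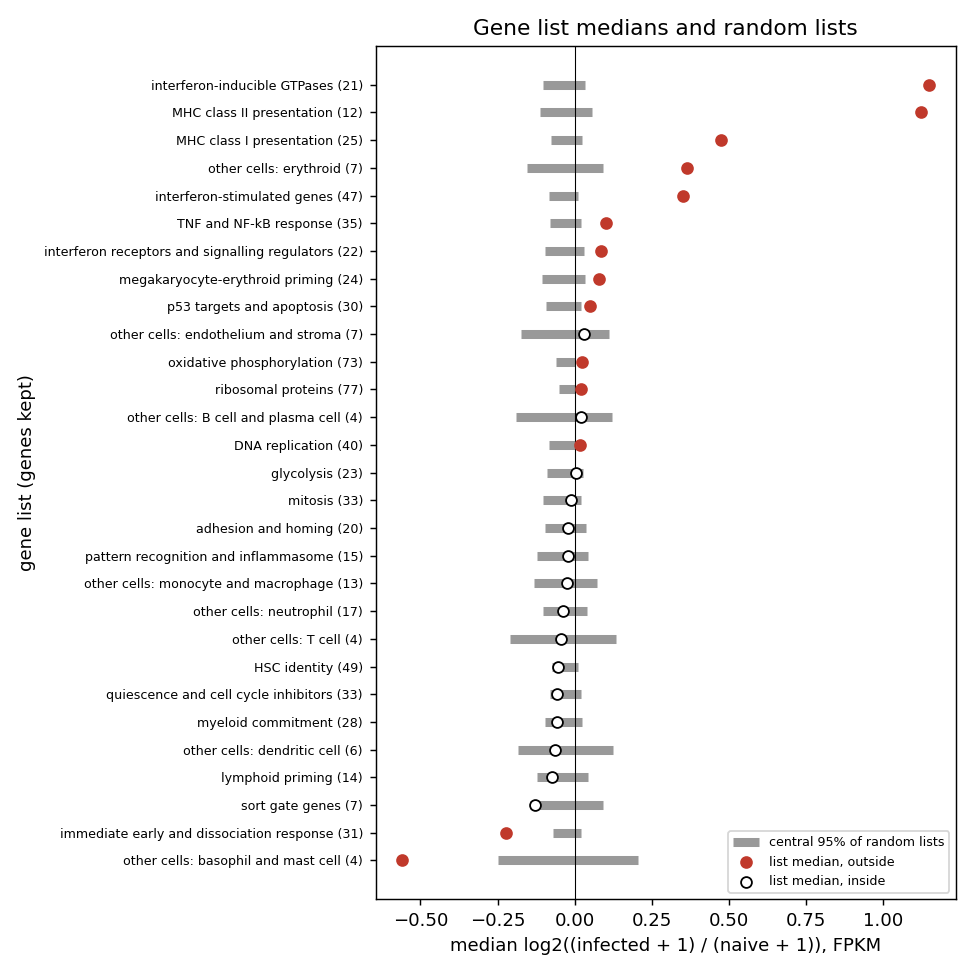
Median log2 ratio of infected over naive FPKM (pseudocount of 1) for each gene list, with its number of kept genes, against the central 95% of 10000 random lists matched in size and mean FPKM (grey bars). Red medians lie outside the bar, 12 above and 2 below, led by interferon-inducible GTPases at 1.15 and MHC class II at 1.12.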

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

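Genes that the authors' test left out held further differences in the direction of the interferon genes. Among 1990 untested genes at 5 FPKM or more in a group, 17 stood at least 1.5-fold higher in infected cells and 5 at least 1.5-fold lower. Of the 17, 12 belong to the lists of interferon-stimulated genes, interferon-inducible GTPases or MHC class I. Beside Irf1 these include, chosen after their values were seen, Irf7 (10.2 and 22.7 FPKM), Irgm2 (20.9 and 44.5 FPKM), Tap1 (36.0 and 70.3 FPKM) and Psmb9 (24.9 and 41.3 FPKM) in naive and infected cells. Among 5687 tested genes at that level, 1.78% lay beyond 1.5-fold in either direction, against 1.11% of the untested ones. No test or replicate value stands behind these differences.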

How the results depend on the processing

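No paired analysis was possible because the table holds 1 pooled value per group. For the same reason other normalizations and tests, leaving out samples, separate technical libraries, set tests, and the agreement and spread of replicates were not run. Pseudocounts do not enter the authors' q-values. Requiring a 2-fold change as well left 43 genes higher and 9 lower, by construction. In the other settings, counts of called genes ran from 74 to 109 higher and from 44 to 88 lower. These settings were filters at 1 and 5 FPKM, and, chosen after seeing the data, q under 0.01 and 0.10, a wider adjustment and leaving out immunoglobulin segments. Lists below the range of random lists numbered 1 without a filter on low values and 1 with a filter at 5 FPKM, against 2. The basophil and mast cell list left that range: without a filter its median, now over markers near 0 as well, was -0.07, and at 5 FPKM it had too few markers for a value. The immediate early list stayed below in both. Lists above the range numbered 12, against 13 without a filter, where the B cell and plasma cell list entered, 11 with the filter at 5 FPKM, where pattern recognition entered and the interferon receptor and DNA replication lists left, and 10 over tested genes only, chosen after seeing the data, where the latter 2 left. The DNA replication median changed sign to -0.0062 with the filter at 5 FPKM, and the cause was not tested. Of 201 list medians under alternatives, 194 kept their place inside, above or below the random range. Their size did depend on the pseudocount. The MHC class II median was 1.59 with 0.1 FPKM and 0.66 with 5 FPKM, and that of interferon-inducible GTPases 1.42 and 0.86. Which of these lists led therefore changed with the pseudocount. Of 215 values for named genes, 213 kept their sign and call, and Igkv4-57-1 and Ighv1-7 no longer passed in the wider adjustment. Depth is unknown, so its limit on low genes cannot be stated.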

Other observations

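Beyond the fixed lists, genes chosen after their values were seen included further risers. Serpina3g, a protease inhibitor of leukocytes, rose from 191 to 319 FPKM and Ly6e, a relative of Ly6a, from 182 to 246 FPKM, both at q-values under 0.05 in the authors' deposited table. The cytokine receptor gene Il12rb1 rose from 1.43 to 2.94 FPKM. Fallers included the regulators of signalling Rgs2 (110 to 81.5 FPKM) and Smad7 (54.6 to 43.6 FPKM), the DNA demethylase Tet2 (8.67 to 6.58 FPKM), the circadian factor Arntl (4.98 to 3.89 FPKM) and the nuclear lamina gene Lmna (27.9 to 20.5 FPKM), also called in the authors' deposited table.

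The test of fragment number below was set after the values had been seen, and the others before. The rise of MHC class II could come from antigen-presenting cells in the infected sort, which the lineage gate should remove. Such cells would bring their other transcripts too. Over 13 B cell markers under 1 FPKM in naive cells, immunoglobulin genes left out, the summed FPKM went from 4.27 to 5.43, 1.27-fold, and stayed at 1.32-fold or less with any single marker left out, while Cd74 alone gained 474 FPKM. Cd79a, a component of the B cell receptor, stood at 0.759 and 0.870 FPKM. The B cell list as a whole lay above the random range without a filter on low values (median log2 ratio 0.07, percentile 98.0). Among the immunoglobulin genes left out, Ighg2c, chosen after its values were seen, was called from 0 to 4.96 FPKM in the authors' deposited table. Class-switched B and plasma cells carry this transcript, but the values do not show which cells it came from. Igkc (45.9 and 38.1 FPKM), chosen in the same way, did not pass. Ighm (26.5 and 18.0 FPKM) did not pass over all genes but fell adjusted over the B cell list alone. So a trace of B or plasma cells stays open, but not as the source of the class II rise. The corresponding sums changed 1.05-fold over 11 monocyte and macrophage markers and 0.772-fold over 7 dendritic cell markers, and the abundant macrophage genes Lyz2 (178 and 178 FPKM) and C1qa (3.91 and 3.32 FPKM), chosen after their values were seen, did not pass in the authors' deposited table. These values argue against each of these cell types as the source of the rise. A shift of which HSCs enter the gate as Ly6a rises was not tested, and a response of the stem cells to infection remains a hypothesis.

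The fall of some immediate early genes could reflect gentler handling of the infected preparation. If heat shock stress were part of it, heat shock genes would be lower too, but their median log2 ratio over 12 genes was 0.10, with the lowest at -0.08. Hspa1a, Hspa1b, Hsp90aa1 and Hspa8 are counted both here and in the immediate early list. The heat shock values argue against less heat shock stress. They leave open other differences in sorting time or handling and infection itself, which pooled values do not separate.

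Some called genes changed little. In the authors' deposited table, 33 of the 163 called genes had a log2 change within 0.32 in either direction, among them Sc5d (9.83 to 11.3 FPKM, q = 1.3e-11), chosen after its values were seen, while 96 tested genes at 10 FPKM or more with larger changes were not called. A candidate explanation is that long or abundant genes yield more fragments and so smaller errors. If that alone decided, genes with as many fragments and a larger change would be called. Among 43 tested genes with a log2 change of 0.32 or more in either direction whose FPKM multiplied by exonic length reached the median of the small-fold calls (length known for 87.9% of the 33), 26 were called and 17 were not, or 60.5% called (Wilson 95% interval 45.6% to 73.6%). The interval takes genes as independent, which genes of the same pooled values need not be, so it is no range over replicates. The share called does not decide the explanation, which stays open. Whether technical replicates entered the authors' test as separate samples is unknown too. Its part in the small-fold calls was not tested, as the table holds no values per library. Loci that hold several genes do not account for the small-fold calls, as 24.2% of the 33 shared a locus with another row, against 29.3% of tested genes.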
